A study of Homo sapiens with 12 samples.

How the data were processed

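The series held 12 samples of total RNA from HCT116, a human colorectal carcinoma cell line, in 4 groups of 3. Cells stably carried a lentiviral construct for the Short isoform of SNHG1 (SNHG1S), for the Long isoform (SNHG1L) or a control vector, and each isoform had its own 3 control samples. The series design text calls the replicates biological. Labelled cDNA was hybridised to a 2-colour Agilent array, with the control in Cy3 and the isoform in Cy5 in every pair, so that 6 arrays held the 12 samples and no dyes were swapped. For each of the 6 arrays, the scanner files of its 2 samples were identical, and each sample was read from its own channel. Of the 6 arrays, 4 (all 3 of SNHG1S and replicate 1 of SNHG1L) came from slide 1 and 2 from slide 2.

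The deposited scanner files gave intensity values on a linear scale: per the file headers, Agilent Feature Extraction 11.5.1.1 measured the median brightness of each spot and of its local background, and wrote a processed signal after background subtraction and dye normalization. A mean signal, which the plan had named, is not a column of these files, and the median signal was used in its place. The authors' deposited series matrix held log2 values for 75217 rows. Its 12 columns shared 1 distribution with a median of 6.32, so they were quantile normalized over samples of both dyes. Each column correlated with the log2 processed signal of its own sample at 0.988 to 0.999 across probes. The centring of genes did not arise, since the columns followed the absolute signal. The submitters' processing notes name limma with no version or step.

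Background was corrected with normexp (offset 50), ratios were normalized by loess within each array with control spots at weight 0, and control spots and spots flagged as outliers were then left out. No spot was saturated. Spots of a probe (2 spots for 49541 probes, 3 spots for 25608) were averaged into 1 log2 ratio, isoform over control, per array. Of 75149 probes, 48727 were tested: those well above background, by the scanner software's flag in more than 0.5 of their spots, in all 3 samples of at least 1 group. The other 26422 were left out. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per isoform to the 6 arrays (lmFit, eBayes), and the difference was SNHG1L minus SNHG1S. P-values were adjusted by Benjamini-Hochberg over probes, and a probe was called at an adjusted p under 0.05. An SD is over the 3 arrays of an isoform, and an SE is from the limma fit. The number of arrays limits the precision.

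Probe IDs in the files are not paired with gene names, and no table used here paired them. Of the IDs, 102 running numbers such as those of the p series happened to equal a synonym in the gene table given with the GRCh38.p14 assembly, which was taken as coincidence and not used, and 1 other ID matched a synonym. SNHG1 itself, the 29 gene lists with 724 different genes fixed before the data were examined, and the median over probes of a gene were therefore not analysed here. Of the listed genes, 2 (GAPDH and PGK1) have control probes that carry their names. The planned rule was to name, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among calls with the same sign on all 3 arrays, and for the difference those with the 3 arrays of an isoform all beyond the 3 of the other. With IDs alone it was narrowed, after the files were seen, to 2 probes per direction. In place of the gene lists, classes in the probe IDs with at least 10 tested probes were tested with camera (preset correlation 0.01, and an estimated correlation). These classes were chosen after the IDs were seen. IDs are printed as in the files, and abbreviations in them are not expanded where no source does so.

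The replicate numbers come from the sample titles. Deviations from the isoform mean were correlated across probes between arrays of the 2 isoforms. Same-numbered arrays gave 0.24 for replicate 1, 0.46 for replicate 2 and 0.23 for replicate 3, and differently numbered arrays gave -0.37 to 0.12. The deviations of an isoform sum to 0 over its 3 arrays, so these values are not separate pieces of evidence. The ratios of SNHG1S replicate 3 correlated less with SNHG1L replicate 3 (0.38) than with replicate 1 (0.49) or 2 (0.51). On this limited ground the numbers were taken to pair the arrays, and fits with the number as a replicate block are given beside the results they move. The fit was tested on simulated data with the real residual spread of the 48727 probes and 200 changed probes. The simulated noise was independent between arrays and between probes and held no dye effect. Real same-numbered arrays deviate together, so the recovered shares and false calls hold for the simulated noise only. For SNHG1S, 67.7% of probes changed by 0.5 on the log2 scale and 90.3% of those changed by 1 were recovered, with 1 false call. For SNHG1L the shares were 63.9% and 100%, with 3 false calls, and for the difference 44.8% and 91.0%, with 3 false calls. Alternatives fixed before the data were examined covered background correction, normalization, the dim-probe filter, outlier spots, slide, unpaired channels, the arrays in the fit, the variance prior, array weights, a fold threshold, the series matrix and leaving out each array.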

Results

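Gene expression was measured in HCT116 cells that stably overexpressed 1 of 2 isoforms of SNHG1, a long noncoding RNA gene that hosts small nucleolar RNAs in its introns, or carried a control vector. There were 3 SNHG1S samples and 3 SNHG1L samples, each hybridised on 1 array with a control sample, which gave 6 arrays and 4 groups of 3 samples. The median spot signal was 139 to 173 intensity units in the Cy3 channel (control) and 136 to 156 in the Cy5 channel (isoform). Between 49.3% and 53.7% of the 75149 probes were well above background in the control samples, and between 60.5% and 70.2% in the isoform samples. The 48727 probes tested comprised 25730 with catalogue-style IDs beginning with A, 15953 of a numbered p series, 4974 of the p series marked v4, and small RNA classes, among them 713 imsncRNA, 253 snoRNA or scaRNA, 80 tRNA, 74 snRNA and 10 rRNA probes. Probes are reported by ID and class, and which of them measure SNHG1 is not settled by the files used here. As the dyes were never swapped, a probe-specific dye effect common to all arrays cannot be told apart from overexpression for probes that move alike with both isoforms. It cancels in the comparison of the isoforms, so it does not by itself make probes differ there.

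The comparison of SNHG1S with its control asked which transcripts changed when the Short isoform was overexpressed. Probe p29032 rose most, by a log2 ratio of 2.04 ± 0.04 (SD, n = 3), or 4.11-fold (limma adjusted p = 4.01e-07), followed by p2330 at 1.90 ± 0.17 (3.72-fold, limma adjusted p = 2.42e-06). The falls were smaller: A_24_P47681 had a log2 ratio of -0.76 ± 0.06 and A_21_P0001246 one of -0.60 ± 0.06 (SD, n = 3, limma adjusted p = 0.000155 and 0.00121). When arrays were only centred on their medians these were -0.19, still called, and 0.01, not called. In the series matrix they were -0.99, called, and -0.89, not called (limma adjusted p = 0.0555). In all, 1995 probes were called, 1345 higher and 650 lower, or 4.09% of those tested. Their median absolute log2 ratio was 0.30, and the 20 probes that changed at least 2-fold were all higher. Probe p2330 belonged to a run of 12 consecutively numbered p probes (2327 to 2338), singled out after its values were seen, of which 9 rose by log2 ratios of 0.67 to 1.90 (1.59-fold to 3.72-fold), against 12 of 12 with median centring. Among the 18 tested p probes within 12 numbers on either side, 0 were called by limma with either isoform, 7 had an unadjusted p under 0.05 with either, and the largest absolute log2 ratio was 0.20. Of all 48727 tested probes, 12829 with SNHG1S and 13326 with SNHG1L had an unadjusted limma p under 0.05, and 4.09% and 6.80% were called. The 2 counts of neighbours alone therefore do not mark an edge of the run. By class, 7 of 80 tRNA probes rose and 0 fell (59 and 1 with median centring, and 0 called with processed signals or the series matrix), 21 of 713 imsncRNA probes rose and 6 fell (361 and 46 with median centring, 2 and 2 with processed signals, 1 and 0 with the series matrix), and 4 of 253 snoRNA or scaRNA probes rose and 1 fell (151 and 10 with median centring, and 0 called with processed signals or the series matrix). With median centring 26456 of all 48727 tested probes were called higher, and the counts in that setting, for the run as well, are to be read beside that share.

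The count of SNHG1S calls was 8598 (5357 higher, 3241 lower) with the replicate number as a replicate block, and 442, 167 and 93 without SNHG1S replicate 1, 2 or 3 and 857 without SNHG1L replicate 3. It was 26456 higher and 3802 lower with arrays only centred on their medians, which moved the median of all tested probes to 0.18, 190 higher and 46 lower with Agilent's processed signals, and 53 higher and 11 lower with the series matrix. The excess of rises depended on the filter for dim probes: 1713 rose and 1420 fell with no filter (75149 probes), and 1619 and 1267 among probes well above background in all 12 samples. In 379 of the 1995 called probes no control sample was well above background, and in 3 no SNHG1S sample was. The 379 could not pass the filter through that control group, so their inclusion rests on other groups. The size of their ratios is uncertain. Of the 20 probes that changed at least 2-fold, 0 were among the 379.

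**Figure D1:**
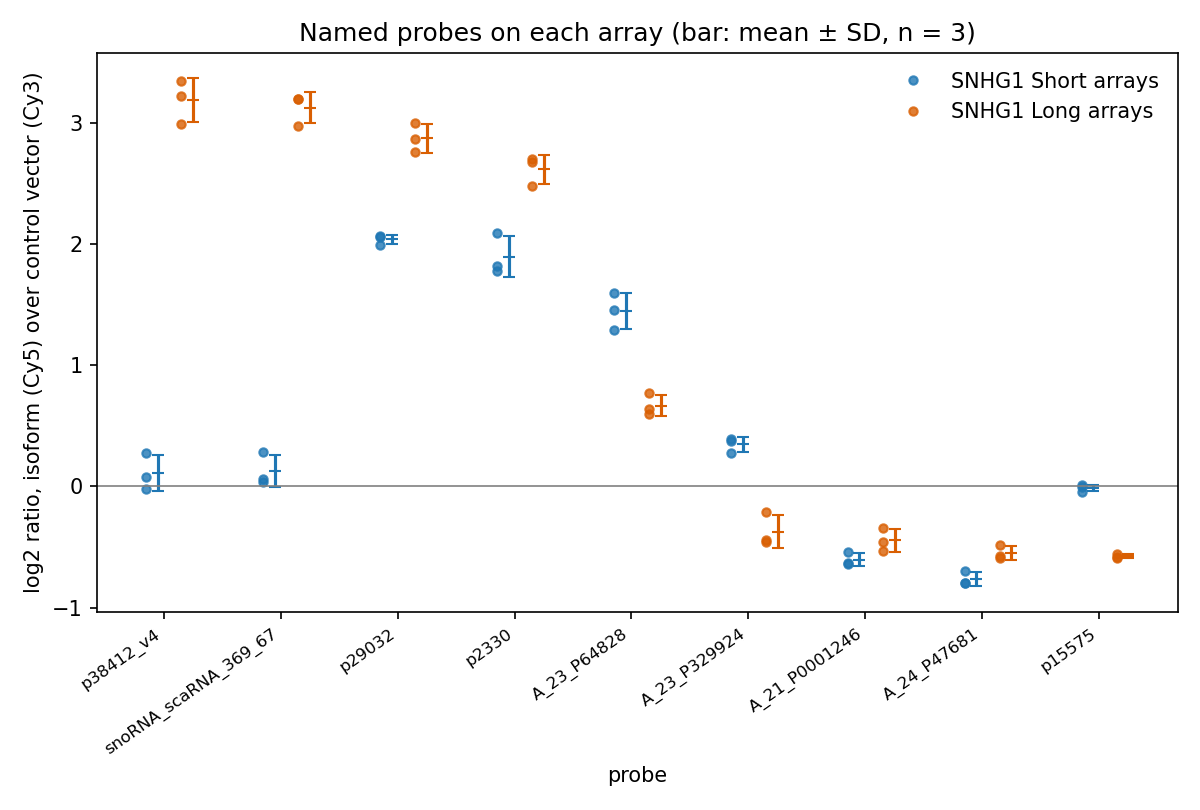
Log2 ratio of isoform (Cy5) over control vector (Cy3) for each named probe on each array: points are arrays, bars the mean ± SD of 3 arrays, blue SNHG1 Short and orange SNHG1 Long. Probes p38412_v4 and snoRNA_scaRNA_369_67 lie near 0 with SNHG1S and near 3 with SNHG1L, and with arrays only centred on their medians the values of A_21_P0001246 with SNHG1S (0.01) and of A_24_P47681 with SNHG1L (0.07) lie above 0.

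The comparison of SNHG1L with its control asked the same of the Long isoform. The largest rises were in p38412_v4, at a log2 ratio of 3.19 ± 0.18 (9.11-fold, limma adjusted p = 2.87e-08), and in snoRNA_scaRNA_369_67, a probe of the small nucleolar RNA class, at 3.12 ± 0.13 (8.71-fold, limma adjusted p = 1.39e-08; SD, n = 3 for both). Probe p29032 reached 2.87 ± 0.12 and p2330 2.62 ± 0.12. The largest falls were in p15575, at -0.58 ± 0.02, and in A_24_P47681, at -0.55 ± 0.06 (limma adjusted p = 0.00105 and 0.00231). With arrays only centred on their medians these were -0.05 and 0.07, neither called. With slide as a term both were -0.59 and no longer called (adjusted p = 0.0678 and 0.0831), as on slide 1 alone (adjusted p = 0.165 and 0.171), and A_24_P47681 was not called in the series matrix (-0.65, adjusted p = 0.0637). In the numbered run, 11 of 12 probes rose (9 with processed signals or the series matrix), and the 9 that also rose with SNHG1S did so by log2 ratios of 1.37 to 2.62 (2.58-fold to 6.14-fold). In all, 3312 probes were called, 2345 higher and 967 lower (6.80% of those tested), with a median absolute log2 ratio of 0.28. All 17 that changed at least 2-fold were higher. Here 7 of 80 tRNA probes rose and 0 fell (64 and 2 with median centring, and again 0 called with processed signals or the series matrix), 11 of 253 snoRNA or scaRNA probes rose and 1 fell (160 and 11 with median centring, 2 and 0 with processed signals, 1 and 0 with the series matrix), and 29 of 713 imsncRNA probes rose and 20 fell (320 and 60, 1 and 1, and 0 called in the same settings). Of the 74 snRNA probes 4 rose and 4 fell (34 and 8, 0 and 1, and 0 called), and 3 of 10 rRNA probes rose and 2 fell (8 and 1 with median centring, and 0 called with processed signals or the series matrix). With median centring 25181 of all 48727 tested probes were called higher.

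The count of SNHG1L calls was 9204 (6111 higher, 3093 lower) with the replicate block, 44 with slide as a term and 21 on slide 1 alone, where 1 SNHG1L array remained and was taken to vary like the SNHG1S arrays. It was 1881, 5340 and 899 without SNHG1S replicate 1, 2 or 3, and 1822, 61 and 34 without SNHG1L replicate 1, 2 or 3. It was 25181 higher and 4508 lower with median centring, 208 higher and 47 lower with Agilent's processed signals, and 26 higher and 4 lower with the series matrix. With no filter on dim probes falls outnumbered rises, with 4047 higher and 4871 lower, while among probes well above background in all 12 samples 1312 were higher and 917 lower. In 1199 of the 3312 called probes no control sample was well above background, and in 1 no SNHG1L sample was. The 1199 could not pass the filter through that control group, so their inclusion rests on other groups. This bears on the split of rises and falls as well as on the size of their ratios, which is uncertain.

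**Figure D2:**
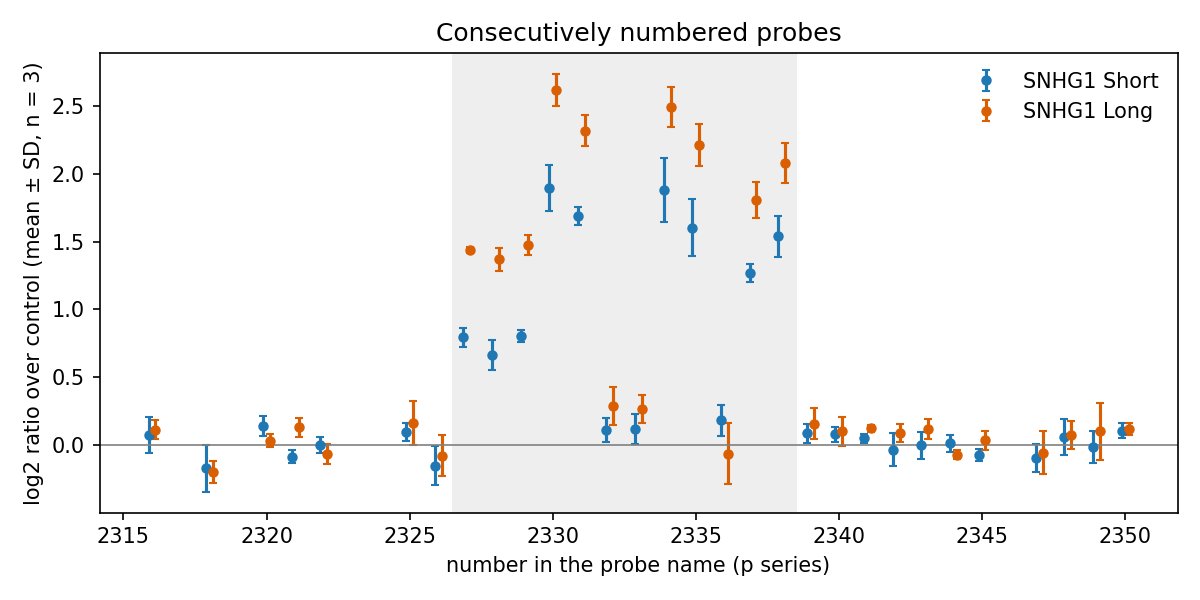
Log2 ratio over control (mean ± SD of 3 arrays) against the number in the probe ID of the p series, with SNHG1 Short in blue and SNHG1 Long in orange. In the shaded run from 2327 to 2338, 9 probes lie between 0.67 and 1.90 with SNHG1S and between 1.37 and 2.62 with SNHG1L, and the largest absolute value among the tested neighbours is 0.20. With median centring all 12 are called higher with SNHG1S, as are 26456 of all 48727 tested probes.

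The median log2 ratio of the tRNA probes was 0.10 ± 0.05 with SNHG1S and 0.11 ± 0.04 with SNHG1L (SD, n = 3 arrays), and camera with the preset correlation placed the class above the other probes in both (adjusted p = 0.00131 and 2.13e-05). With an estimated correlation neither held (adjusted p = 0.312 and 0.415). The medians over tRNA probes of the fitted ratios, 0.06 and 0.11, were 0.35 and 0.44 with median centring, where those of all tested probes were 0.18 and 0.17, and 0.08 and 0.11 with processed signals. The 16 tested RNA probes with no class in their ID had medians of 0.14 ± 0.08 and 0.23 ± 0.20 (camera adjusted p = 0.0107 and 0.00013, and adjusted p = 0.312 and 0.415 with an estimated correlation), but the medians over probes with SNHG1S and SNHG1L were -0.10 and 0.07 with processed signals, -0.16 and 0.06 with the series matrix, and 0.82 and 0.92 with median centring. With SNHG1S the p series marked v4 was also placed above, and the A series below, the other probes (camera adjusted p = 0.0421 and 0.0107), which became adjusted p = 0.312 and 0.0534 with an estimated correlation. Of the 10 classes tested, camera called 0 between the isoforms, and 1 had an unadjusted p under 0.05. The snoRNA or scaRNA class had that p, at 0.0147 unadjusted and 0.147 adjusted, with medians of 0.01 ± 0.01 in SNHG1S and 0.04 ± 0.02 in SNHG1L. Its medians over probes were 0.23 and 0.25 with median centring, -0.005 and 0.05 with processed signals, and -0.002 and 0.04 with the series matrix. No class call changed with the replicate block.

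The difference between the isoforms asked which probes differed between Long and Short. Probes p38412_v4 and snoRNA_scaRNA_369_67 separated the isoforms most. Whether these 2 probes measure the introduced RNA itself or a response to it was not tested. Their log2 ratios with SNHG1S, not called, were 0.11 ± 0.15 and 0.13 ± 0.13 (SD, n = 3), and SNHG1L exceeded SNHG1S by 3.08 (SE 0.11) and 2.99 (SE 0.09), or 8.43-fold and 7.97-fold (limma adjusted p = 1.88e-06 and 1.29e-06). Probe A_23_P64828 rose with both isoforms but less with SNHG1L (1.45 ± 0.15 against 0.67 ± 0.09; difference -0.78, SE 0.09). Probe A_23_P329924 was higher with SNHG1S and lower with SNHG1L (0.35 ± 0.06 against -0.37 ± 0.14; difference -0.72, SE 0.09), and both had a limma adjusted p of 0.0431, a call lost without any 1 of the 6 arrays. In all, limma called 10 probes, 7 higher with SNHG1L and 3 lower, and 3579 had an unadjusted p under 0.05. The numbered run supplied 3 of the 7, and across its 9 raised probes SNHG1L exceeded SNHG1S by 0.54 to 0.72. Outside the run, p29032 and the probe numbered next to it, p29031, were also among the 7. Probe p29031 was at 0.80 ± 0.05 with SNHG1S and 1.48 ± 0.05 with SNHG1L (difference 0.67, SE 0.07). The count was 21 (13 higher, 8 lower) with the replicate block, 6 (2 higher, 4 lower) with slide as a term and 3 on slide 1 alone. It was 2, both higher with SNHG1L, without any 1 of the 6 arrays, and likewise 2 higher and 0 lower with Agilent's processed signals, with scale normalization and with the series matrix, and 3 higher and 0 lower with no background correction.

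Most probes called with both isoforms moved the same way. Of the probes called in both comparisons, 807 had the same sign, 580 higher and 227 lower, and 2 had opposite signs. Lists of the same sizes drawn independently would share 64.7 higher and 12.9 lower. The 2 comparisons are not independent, since they share the same estimate of the spread and same-numbered arrays deviate together. These numbers are therefore not a chance level for the overlap. The controls of the isoforms were separate samples, but the dye orientation was shared. Across the tested probes, which are not independent replicates, the 2 log2 ratios correlated at 0.62 (Pearson) and 0.59 (Spearman). The overlap was 3600 with the replicate block and 32 with slide as a term. It was 231, 142 and 73 without SNHG1S replicate 1, 2 or 3 and 400, 44 and 29 without SNHG1L replicate 1, 2 or 3. Its split was 22192 higher and 2430 lower with median centring, 16 higher and 1 lower with the series matrix, and 548 higher and 330 lower among probes well above background in all 12 samples. With no filter on dim probes it turned to 834 higher and 904 lower.

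**Figure D3:**
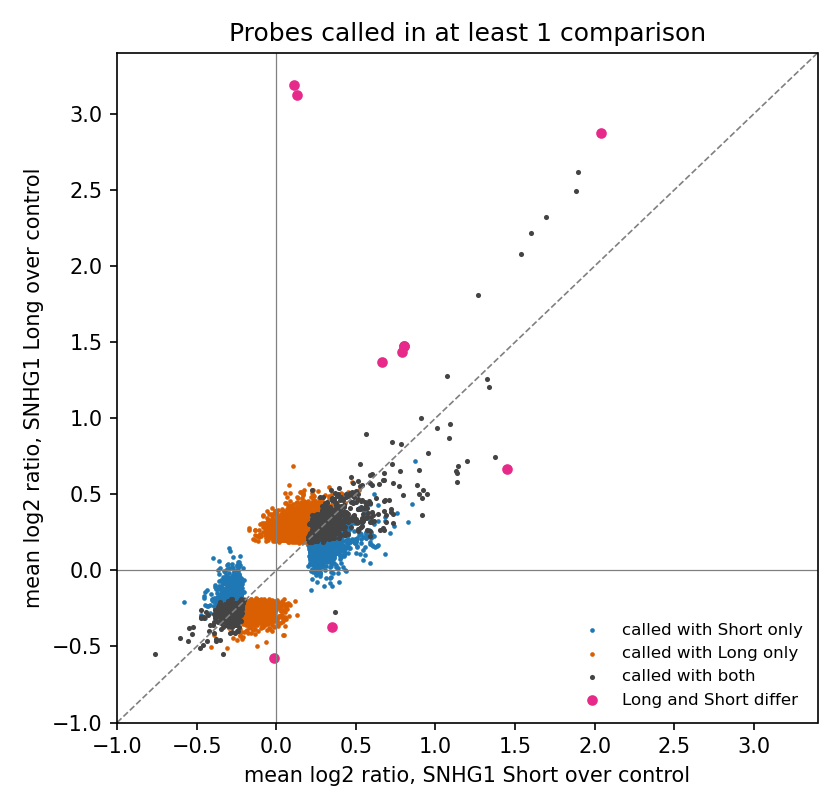
Mean log2 ratio with SNHG1 Long against that with SNHG1 Short (3 arrays each) for every probe called in at least 1 comparison, coloured by comparison, with the dashed line at equal ratios. Of the probes called with both isoforms, 807 lie in the quadrants of equal sign, and the 10 larger points are probes that differ between the isoforms.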

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

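The tests of the slide, both tests of a dye effect and the swaps of same-numbered arrays together were chosen only after the results were seen (that no array was dye-swapped was known from the labels). The limma test of the difference between isoforms called 10 probes. Among the probes named in the report, the SNHG1L minus SNHG1S log2 ratio was 3.08 for p38412_v4, 2.995 for snoRNA_scaRNA_369_67, 0.83 for p29032, -0.56 for p15575, -0.78 for A_23_P64828 and -0.72 for A_23_P329924.

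The slide was weighed for these 10 probes, because SNHG1L replicate 1 shared slide 1 with the 3 SNHG1S arrays while the other SNHG1L arrays lay on slide 2. If the slide made the difference, that array would sit with SNHG1S. Without that array 2 of the 10 probes were still called, p38412_v4 and snoRNA_scaRNA_369_67, so their choice does not rest on it. With slide as a term, which leaves the difference to slide 1, both of these 2 stayed called at 3.23 (SE 0.14) and 3.07 (SE 0.14), against 3.08 (SE 0.11) and 2.995 (SE 0.09) without the term. This argues against the slide as the whole cause for these 2, though 1 SNHG1L array carries it. Of the other 8, whose calls used that array, 0 stayed called with slide as a term. Their absolute differences went from 0.56 to 0.83 (SE 0.07 to 0.09) to 0.56 to 0.82 (SE 0.10 to 0.13), with a larger SE and 1 residual degree of freedom fewer, and for these 8 the slide cannot be told apart from the isoform. On slide 1 alone 3 probes were called, 2 of them among the 10. There are 10 splits of the 6 arrays into groups of 3, too few for a share under 0.05: 1 of the 10 gave as many calls, the real one with 10, and the highest of the others was 0, as it was among the other splits that part all 3 same-numbered pairs. The isoform, as the design names it, stays open as the explanation.

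A dye effect was weighed for the 807 probes called with both isoforms in the same direction. With 0 dye-swapped arrays, a probe-specific dye effect cannot be told apart from overexpression for these probes. For 6 of them the difference between isoforms was also called, with the 3 arrays of an isoform all beyond the 3 of the other. A dye effect common to all arrays does not give such a difference by itself. The absolute differences of these 6 probes were 0.65 to 0.83 (SE 0.07 to 0.09). The count was 0 without any 1 of the 6 arrays, with slide as a term, on slide 1 alone, at 2-fold or more, with processed signals, with scale normalization and with the series matrix, 1 with no background correction or no filter on dim probes, 5 with unpaired channels, 6 to 8 with outlier spots kept, the filter on all 12 samples, median centring, an intensity trend or array weights, and 12 with the replicate block. In the 21 other settings the 6 differences kept their sign, at 0.50 to 0.92 and at least 2.68 SE from 0. Their unadjusted limma p was at most 0.0212. These settings refit all or some of the arrays on which the 6 probes were chosen, and several cannot change the differences. The kept sign is therefore no separate support. Without 1 array the 6 differences were 0.61 to 0.89 (SE 0.07 to 0.11), with 1 residual degree of freedom fewer, so those calls did not end because the differences shrank to 0. How much the degrees of freedom, the spread and the adjustment each did was not tested. The 6 probes were chosen by their called difference, so that call cannot serve as a separate test of a common dye effect. They are also among the 8 probes above for which the slide cannot be told apart from the isoform. A common dye effect stays open for part of the ratios of these 6 and for the rest of the 807. Swapping isoform and control labels on each array alone gave an overlap as large in 1 of 32 ways, the real one (highest other 2), but same-numbered arrays deviate together and are not independent. Swapping them together gave as large an overlap in 1 of 4 ways, the real one with 807 (highest other 0), too few for a share under 0.05. For SNHG1S alone and for SNHG1L alone, 1 of 4 swaps each gave as many calls as the real 1995 and 3312, the highest other was 0, and 4 swaps are too few for a share under 0.05.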

How the results depend on the processing

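The replicate block for comparisons with control, slide 1 alone and all class tests were added after the data were seen. Apart from leaving out an array, 16 settings were run for each count (15 for the difference, which its own 3 arrays cannot give). Those that moved a count by over 1.5 times are given below, and the other 3 for SNHG1S, 6 for SNHG1L, 6 for the difference and 4 for both stayed within that. Probes p29032 and p2330 with SNHG1S, and p38412_v4 and snoRNA_scaRNA_369_67 with SNHG1L and in the difference, kept their direction and call in every setting, leave-outs included. The 12 named log2 ratios gave 260 values in other settings, of which 217 kept direction and call, 41 lost the call and 2 reversed. Several settings, such as leaving out an array of the other isoform, cannot change a ratio over control, so its direction was fixed there. Both reversals came with median centring: A_21_P0001246 with SNHG1S (0.0051) and A_24_P47681 with SNHG1L (0.073). The shift of all probes in this setting was smaller. Their median went from 0.018 to 0.18 with SNHG1S and from 0.022 to 0.17 with SNHG1L. These 2 probes went from -0.60 to 0.0051 and from -0.55 to 0.073, so that shift alone does not account for the reversals. The cause was not tested further. The calls of A_23_P64828 and A_23_P329924 in the difference were lost in 15 of 21 settings each, with limma adjusted p from 0.00721 to 0.815 apart from slide 1 alone. The differences themselves stayed at -0.92 to -0.68 and at -0.80 to -0.56. The gene list tests and the median over probes of a gene were not run.

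SNHG1S calls, 1995 as reported, were 1219 with no background correction, 236 with Agilent's processed signals, 30258 with median centring, 5115 with scale normalization, 3133 with no filter on dim probes, 550 on its own 3 arrays, 3238 with an intensity trend, 6445 with array weights, 20 at 2-fold or more, 64 with the series matrix and 550 on slide 1 alone. SNHG1L calls, 3312 as reported, were 255 with processed signals, 29689 with median centring, 8918 (4047 higher, 4871 lower) with no filter, 44 with slide as a term, 1636 on its own 3 arrays, 17 at 2-fold or more, 30 with the series matrix and 21 on slide 1. Differing probes, 10 as reported, were 3 with no background correction, 2 with processed signals, 2 with scale normalization, 3 with no filter, 6 with slide as a term, 2 at 2-fold or more, 2 with the series matrix and 3 on slide 1. Probes called with both, 807 as reported, were 71 with processed signals, 24622 with median centring, 1266 with scale normalization, 1738 (834 higher, 904 lower) with no filter, 32 with slide as a term, 233 on own arrays, 1747 with array weights, 10 at 2-fold or more, 17 with the series matrix and 13 on slide 1.

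With the replicate block the counts were 8598, 9204, 21 and 3600 in the same order, and it changed no class call. Unpaired separate channels (no replicate block) gave 605, 937 and 181 for SNHG1S, SNHG1L and both. Leaving out each array gave 93 to 1656 for SNHG1S, 34 to 5340 for SNHG1L, 2 for the difference in each of 6, and 29 to 400 for both. With an estimated correlation, the camera class calls went from 4 to 0 with SNHG1S and from 2 to 0 with SNHG1L. The cause of these moves was not tested, except that leave-outs and slide 1 alone have fewer arrays and the fold threshold removes small ratios. Signal over background limits the rest: 26422 probes were not tested as too dim.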

Other observations

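The control probes named for housekeeping genes were also read. The log2 ratio of the GAPDH probes, for a glycolytic enzyme, was 0.23 ± 0.05 (3' probe) and 0.13 ± 0.09 (5' probe) with SNHG1S, and 0.26 ± 0.15 and 0.13 ± 0.04 with SNHG1L (SD, n = 3), while Agilent's processed signals gave 0.0046 and -0.00063 with SNHG1S and 0.12 and 0.05 with SNHG1L, and median centring gave 0.86 and 0.71 with SNHG1S and 0.94 and 0.75 with SNHG1L. The PGK1 probes, for another glycolytic enzyme, had opposite signs, except with median centring, where both were above 0: -0.10 ± 0.10 (3') and 0.14 ± 0.04 (5') with SNHG1S, and -0.08 ± 0.04 and 0.25 ± 0.10 with SNHG1L. Of the ERCC control probes, which target no human RNA, 2 were well above background in 12 of 12 samples: ERCC-00043_129 at 0.18 ± 0.002 with SNHG1S and 0.18 ± 0.02 with SNHG1L, and ERCC-00012_90 at 0.09 ± 0.01 and 0.09 ± 0.06. With median centring they were at 0.38 and 0.36, and at 0.30 and 0.29. The slope of observed on expected log ratios of the spike-in controls, per the file headers, was 0.516 to 0.592 and out of the software's range on all 6 arrays. A slope under 1 means that the spike-in log ratios came out smaller than expected. Whether this holds for the other probes, and so for the fold changes and 2-fold counts above, was not tested.

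The run of numbered p probes was weighed next. It was noticed in the fitted values, and all its tests were written after that. The test by shuffles was chosen only after the result was seen, since it counts the run itself, with a window of the length of the run. The results of the other 2 tests had not been seen. A blemish of the slide surface would raise neighbouring spots, but the 248 spots of other tested probes within 2 rows and columns had a median log2 ratio of -0.00073. Of 1000 shuffles, 0 put as many as the 9 strongly raised probes within 12 consecutive numbers (highest 2), but as the run prompted this count, it does not decide on placement by chance. A candidate explanation is that consecutive p numbers often belong to the same transcript: outside the run, mean signals over 9639 pairs of consecutive numbers correlated at 0.209 (Spearman), above the highest of the shuffles, 0.029. The log2 ratios of these pairs correlated less, at 0.088 with SNHG1S and 0.102 with SNHG1L (Spearman), and were not set against shuffles. Another ordering of the numbers, by signal for example, stays open, and whether the run measures the introduced RNA was not tested.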
